A study of Homo sapiens with 19 samples.

How the data were processed

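The series holds spatial transcriptomics of formalin-fixed human biopsies on Visium slides, in which each barcoded spot captures the RNA of a small tissue area that can hold several cells. The 19 libraries fall into 4 groups by the submitters' labels: 7 of colon with an immune-related adverse event (irAE) of checkpoint blockade, 8 of healthy colon, 2 of skin irAE and 2 of psoriasis. Libraries are named here by group and by the replicate number in their titles. The labels do not say whether libraries of a group came from separate donors, so p-values measure the spread between these libraries, which may in part be technical.

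The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and spot, not normalised. The authors made them with Space Ranger 1.3.0 on the genome build GRCh38, and Seurat is also named, per the submitters' processing notes. The probe set, the annotation release and the version of Seurat were not given in the sources used here. The table held 17943 genes and 10796 spots over tissue, of which 12 had 0 UMIs. The sum of counts equalled the deposited total, and the number of detected genes the deposited number, in all 10796 spots. A probe panel counts only the transcripts it targets, so a gene outside the table was not analysed here.

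Spots are not replicates, so the counts were summed over all spots of each library. XIST, TSIX and Y-linked genes, 10 in all, were left out before any test. No 2 replicates of a group agreed within counting noise: the smallest chi-square per degree of freedom between 2 replicates was 4.98. Total UMIs ran from 3587184 to 10514070 in colon irAE and from 693082 to 4288355 in healthy colon, so low genes were measured less precisely in healthy colon. Intervals on counts and limits from a count of 0 cover counting error only.

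The groups of each tissue were compared with edgeR 4.0.16 (quasi-likelihood F test with robust dispersion, TMM factors, filterByExpr) in R 4.3.3, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. The colon fit had 12347 genes, 13 residual degrees of freedom and a biological coefficient of variation of 0.473. The skin fit had 12932 genes, 2 residual degrees of freedom and a biological coefficient of variation of 0.392. TMM factors lay between 0.788 and 1.183 in colon and between 0.825 and 1.216 in skin. Log2 fold changes are irAE over the comparison group, with the standard error (SE) of the fit. Group levels are means of CPM, the counts scaled to a common library total, with the standard deviation (SD) between libraries.

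Gene lists for cell types and pathways, 43 in all and 37 per tissue, were fixed with the tests, the named-gene rule and most alternatives before the data were examined. Of their 482 genes, 464 were in the table, 2 of them under an older symbol. Lists with at least 3 tested genes were tested with camera in limma 3.58.1, with the inter-gene correlation preset at 0.01, and again with an estimated correlation and with fry. Camera compares a list with the other genes, while fry tests whether the list's own genes moved one way on balance. A list score is the mean log2 CPM of all its genes in the table per library, with a prior count of 1. Colon scores were compared by a two-sided exact permutation test over 6435 splits, whose smallest possible p is 0.000155. For 2 libraries against 2 no permutation test could pass, so skin scores have no p.

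The share of spots with a UMI of a gene was taken after thinning each colon spot to 1800 UMIs, a depth set from spot totals alone, and each skin spot to 900. Thinning left out 604 spots of colon irAE, 1907 of healthy colon, 513 of skin irAE and 104 of psoriasis as too shallow. The summed CXCL9, CXCL10 and CXCL11 UMIs in spots with a UMI of any of 8 T cell genes were set against those in the other spots as a log2 ratio per library, with 0.5 counts added to each sum. An exact sign-flip test compared the ratios with 0. Spots of each library were also divided at the library's median share of UMIs from 9 fixed epithelial markers, and both parts were fitted in edgeR with the library as a block and the markers left out. Such parts are ranges of a score and not cell types.

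The genes named in the text follow a fixed rule. It takes a panel of 14 genes whatever their result, and the 8 largest rises and 8 largest falls per tissue among passing genes with a mean of at least 20 CPM and libraries that overlapped by at most 1 between groups (none in skin). It adds up to 4 members of each list by smallest p. Some genes that the rule takes are not reported here. Polymorphic HLA genes and genes with common germline deletions are not named. Gene positions are from GENCODE v29 on GRCh38, in which 17803 of the symbols were found, and are counted from 1.

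The fits were tested on simulated counts with 100 changed genes per fold, 99 of the 4-fold ones being tested in the skin spots. In the colon comparison, over 12243 genes, edgeR called 21% of genes changed 2-fold and 76% of genes changed 4-fold, with 3 calls among unchanged genes. On the same counts DESeq2 called 41% and 87%, with 16.9% of its calls among unchanged genes, and limma-voom 15% and 72%, with 3.3%. In the skin comparison, over 12681 genes, edgeR called 2% and 24%, and 7 calls, 21.2% of all calls, were among unchanged genes. There DESeq2 called 4% and 44%, with 31.4% of its calls among unchanged genes, and limma-voom 1% and 21%, with 29%. For the epithelium-poor against the epithelium-rich spots of colon irAE, over 12002 genes, edgeR called 77% and 96%, with 7.5% of calls among unchanged genes, and for the difference of that effect between groups 39% and 80%, with 4.8%. In skin irAE, over 12597 genes, the figures were 19%, 71.7% and 13.5%, and for the difference 3%, 53.5% and 8.2%. For these parts of the spots, the simulated dispersion was that between libraries divided by 4. That value was set and not estimated from the parts, so the rates depend on it. A list of 16 genes changed 2-fold in simulated colon had a camera adjusted p of 1.8e-27, and 6.99e-07 with an estimated correlation, with 1 other list called. In simulated skin, a list of 17 genes so changed had 2.22e-07, and 0.883 with an estimated correlation, with 0 others called among 33. The simulated genes varied independently of each other. The counts of other lists called therefore do not test how often the preset correlation calls unchanged lists in the real libraries.

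Alternatives covered DESeq2 1.42.0 and its size factors in edgeR, scaling by library size alone, limma-voom with quality weights, other count filters, spots with at least 500 UMIs, libraries thinned to 693082 UMIs in colon and 3201708 in skin, removal of the 33 immunoglobulin genes, mean log-normalised spots, 1 fit of all 4 groups, log library size as a covariate, the replicate number as a block, and leaving out each library in turn. Alternatives chosen after seeing the data were the 4 shallowest healthy libraries left out, smooth muscle or olfactory receptor levels as covariates, lists without polymorphic HLA genes, each epithelial part of the spots alone, and another pseudocount for the chemokine ratio. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.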

Results

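Gene expression was measured on tissue sections of colon and skin from checkpoint blockade-related inflammation, in which immune-related adverse events (irAE) take the form of colitis and dermatitis, and from healthy colon and psoriasis, a chronic inflammatory skin disease. The 7 colon irAE libraries held 4370 spots, the 8 healthy colon libraries 4320, the 2 skin irAE libraries 1155 and the 2 psoriasis libraries 951. Library totals ran from 3587184 to 10514070 UMIs in colon irAE (median 5856238) and from 693082 to 4288355 in healthy colon (median 1613186). Skin irAE replicates 8 and 20 held 3201708 and 4372993 UMIs, and psoriasis replicates 1 and 2 held 5911025 and 13020014. In colon irAE replicate 9, 57.7% of spots had under 500 UMIs, as had 43.3% in skin irAE replicate 8. Immunoglobulin genes took 4.62% to 10.9% of UMIs in colon irAE and 0.41% to 4.84% in healthy colon.

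The first comparison asked which genes differ between colon irAE and healthy colon, with attention to resident T cells and type 1 cytokines. The interferon-induced chemokines that draw CXCR3-bearing T cells were far higher in colon irAE. CXCL9 (chromosome 4, 76001275 to 76007488) stood at 191 ± 136 CPM (SD, n = 7) against 2.65 ± 2.25 in healthy colon (n = 8), a log2 fold change of 5.93 ± 0.60 (SE). CXCL10 (chromosome 4, 76021117 to 76023497) rose by 4.50 ± 0.61 and CXCL11 (chromosome 4, 76033682 to 76041415) by 4.91 ± 0.68 on the log2 scale. CXCR6, a chemokine receptor of tissue-resident T cells (chromosome 3, 45940933 to 45948353), rose by 3.43 ± 0.47, and GZMB, the cytotoxic protease granzyme B (chromosome 14, 24630954 to 24634267), by 3.77 ± 0.83. The water channel gene AQP8 (chromosome 16, 25215731 to 25228940) fell from 1379 ± 1189 CPM to 9.62 ± 13.5, a log2 fold change of -7.14 ± 1.23.

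By edgeR's quasi-likelihood test, 1410 genes were higher and 1576 lower in colon irAE among 12347 tested. Scaled by library size alone, which moved the median log2 fold change of all genes to 0.17, the split was 1966 higher and 982 lower. On mean log-normalised spots limma called 5547 higher and 181 lower, with 442 of the 2986 calls changing sign, and limma-voom called 2953 and 2604 on the summed counts. With log library size, which differed between the groups, in the same fit, 22 genes were higher and 33 lower, and without the 4 shallowest healthy libraries (replicates 3, 10, 14 and 15) 625 and 540. Healthy colon replicate 13 stood apart in its smooth muscle score (11.2, the others 1.77 to 3.90), and with that score in the fit 1097 genes were higher and 819 lower.

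Among the fixed panel in colon, TNF (chromosome 6, 31575567 to 31578336) rose by 1.70 ± 0.52 (edgeR adjusted p = 0.025), ITGAE, the integrin chain of intraepithelial resident T cells, by 1.68 ± 0.53 (adjusted p = 0.028) and FOXP3, the regulatory T cell factor (chromosome X, 49250436 to 49264826), by 2.65 ± 0.60 (adjusted p = 0.0045). CD8A differed by 1.55 ± 0.67 (edgeR adjusted p = 0.103) and CD69, an activation and residency marker, by 1.09 ± 0.50 (adjusted p = 0.124), and neither passed. The call of TNF ended without colon irAE replicate 5 (1.59) or 6 (1.39) or healthy colon replicate 15 (1.56). That of ITGAE ended without irAE replicate 2 (1.5) or 6 (1.53) or healthy colon replicate 3 (1.57), 10 (1.56) or 14 (1.57). IFNG, the gene of interferon-gamma (chromosome 12, 68154768 to 68159747), fell under the count filter: it had 337 counts in colon irAE and 9 in healthy colon, a ratio per UMI of 13.1 (counting interval 6.83 to 29). IL17A had 94 and 13 counts (ratio 2.54, 1.41 to 4.94), IL23A 61 and 4 (ratio 5.35, 1.99 to 20.3), and IL13 5 and 4 (ratio 0.438, 0.0943 to 2.21).

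**Figure D1:**
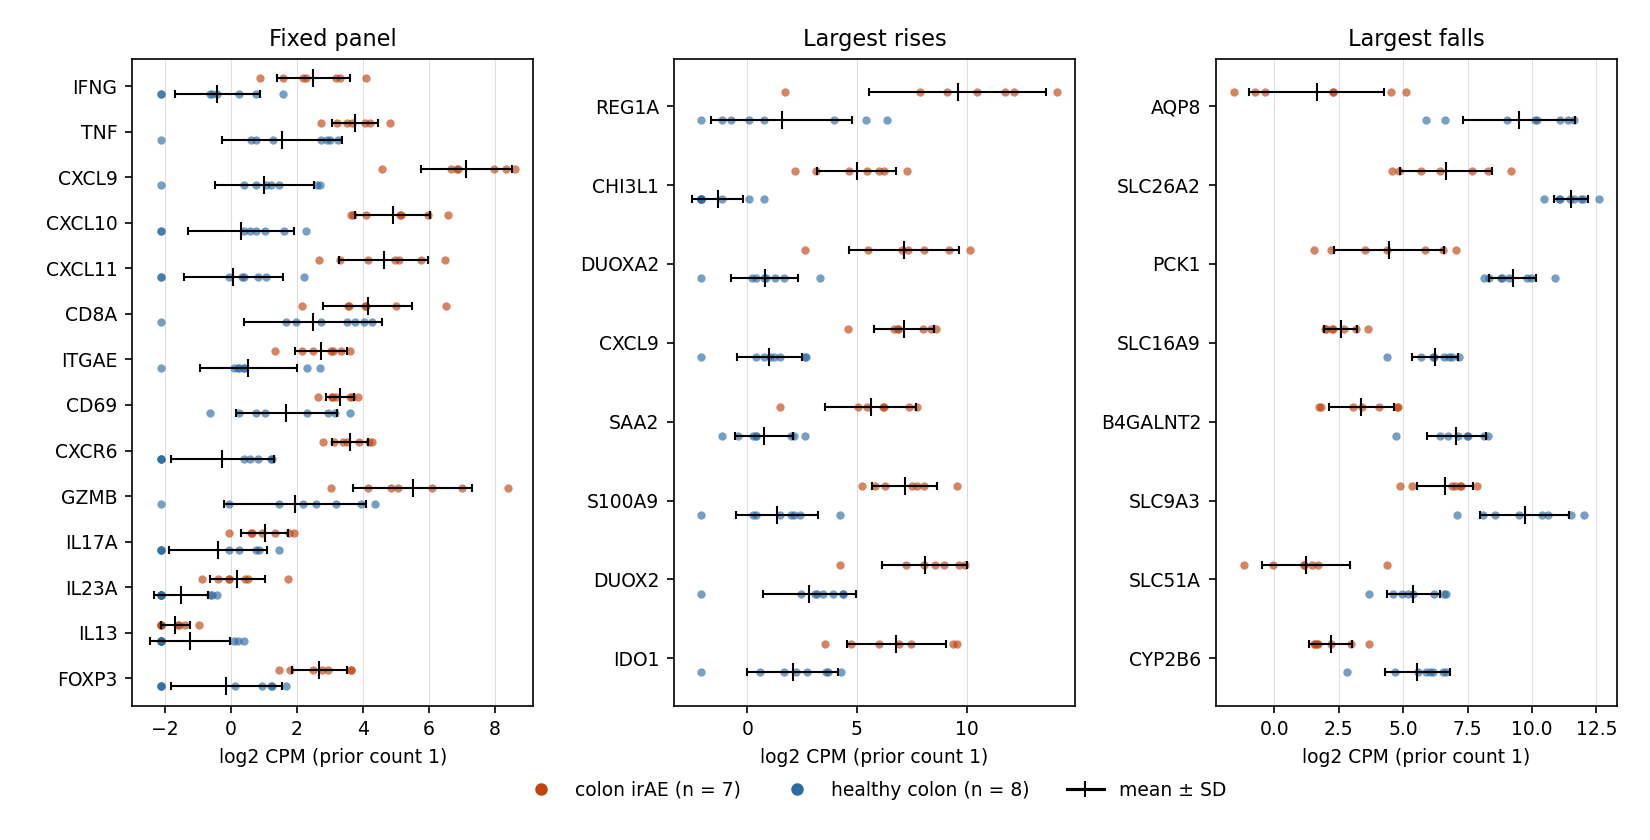
Expression of the fixed panel, the largest rises and the largest falls in colon, as log2 CPM with a prior count of 1. Each dot is a library, with the mean and SD of 7 colon irAE and 8 healthy colon libraries. The 7 irAE libraries lie between 23.5 and 393 CPM for CXCL9, above the highest healthy library at 6.26 CPM.

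The largest rises in colon were those of REG1A, a regenerating-family gene of injured epithelium (chromosome 2, 79120362 to 79123419), at 7.79 ± 1.58, of CHI3L1, a chitinase-like glycoprotein (chromosome 1, 203178931 to 203186749), at 7.52 ± 0.91, and of DUOXA2, the maturation factor of the epithelial peroxide generator DUOX2 (chromosome 15, 45114321 to 45118421), at 6.74 ± 0.94. They were followed by CXCL9, SAA2 (5.52 ± 0.80), S100A9 (5.37 ± 0.74), DUOX2 (5.28 ± 0.71) and IDO1, a tryptophan-degrading enzyme (5.17 ± 0.90). CHI3L1 had 4 counts in healthy colon against 2633 in irAE, a ratio of 231 (counting interval 90.0 to 848). After AQP8, the largest falls were those of the sulphate transporter SLC26A2 (-4.12 ± 0.67), the gluconeogenic enzyme PCK1 (-4.0 ± 0.77), SLC16A9 (-3.77 ± 0.40), B4GALNT2 (-3.59 ± 0.57), the sodium-proton exchanger SLC9A3 (-3.57 ± 0.70), the bile acid transporter chain SLC51A (-3.56 ± 0.75) and CYP2B6 (-3.50 ± 0.52).

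Camera with the preset correlation called 20 of the 34 colon lists higher and 2 lower, and fry 23 and 2. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.052, and 27 of 37 list scores passed the exact permutation test after adjustment. In random regroupings of the 15 colon libraries, 10 of 100, the real one included, called at least 22 lists. In the IFN-gamma response list, 19 of 23 genes rose, 0 fell and 4 did not pass, and 21 rose adjusted over the list alone (camera adjusted p = 7.04e-18; adjusted p = 0.054 with an estimated correlation). The guanylate-binding protein GBP5 rose by 3.98 ± 0.41. In the type I interferon response list 6 of 19 rose, as many adjusted over the list alone, among them SIGLEC1 (2.15 ± 0.39) and ISG15 (1.46 ± 0.43; not passing without colon irAE replicate 6, at 1.06), with an adjusted p = 0.413 with an estimated correlation.

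T cell genes rose together in colon irAE. Of 13 in the T cell list, 10 rose, 0 fell and 3 did not pass, and 12 rose adjusted over the list alone, with CD2 at 2.84 ± 0.48 (camera adjusted p = 0.123 with an estimated correlation). In the CD8 and cytotoxic list 9 of 11 rose (10 adjusted over the list alone), with GZMH at 4.10 ± 0.56 and the pore-forming PRF1 at 3.55 ± 0.54 (adjusted p = 0.080 with an estimated correlation). In the tissue residency list 3 of 7 rose (3 adjusted over the list alone): CXCR6, ITGAE and PRDM1 (1.72 ± 0.32), while RUNX3, at 1.28 ± 0.56, did not pass except without healthy colon replicate 1, at 1.94 (adjusted p = 0.052 with an estimated correlation). Its score was 3.09 ± 0.42 in irAE and 1.13 ± 0.67 in healthy colon (exact permutation p = 0.000155, the smallest possible, 7 of 7 irAE libraries above all healthy ones). In the recirculating lymphocyte list only IL7R rose (1.95 ± 0.46), 1 of 6 and 1 adjusted over the list alone, and the list did not pass.

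In the Th1/Tc1 list 10 of 11 genes rose (11 adjusted over the list alone), including STAT4 (3.13 ± 0.59) and the master regulator TBX21 (2.82 ± 0.59; adjusted p = 0.067 with an estimated correlation). The Th17 list had 3 tested genes, of which IL23R fell (-1.73 ± 0.45) and 2 did not pass, KLRB1 (1.10 ± 0.47) among them. Adjusted over the list alone 1 rose and 2 fell, its median was -1.02, its score over all 11 genes was higher in irAE by 0.67, and camera did not call it. The score rests mostly on genes under the count filter, so it may differ with library depth, which was not tested. In the Th2 list CCL18 (5.03 ± 0.74) and IL1RL1 (2.37 ± 0.66) rose and IL4R fell (-0.86 ± 0.30), 2 and 1 of 5 as adjusted over the list alone, and the list did not pass. IL4R did not pass without colon irAE replicate 1, 2, 8, 9 or 10 or healthy colon replicate 1, 2, 3, 10, 14 or 15, at -0.91 to -0.68. Regulatory T cell genes rose in 7 of 8 (7 adjusted over the list alone), among them TNFRSF4 (2.17 ± 0.41) and ICOS (2.36 ± 0.48; adjusted p = 0.067 with an estimated correlation). Immune checkpoint genes rose in 10 of 11 (10 adjusted over the list alone), with PDCD1, the gene of PD-1, at 3.51 ± 0.62, CTLA4 at 2.61 ± 0.54 and HAVCR2 at 2.30 ± 0.40 (adjusted p = 0.052 with an estimated correlation).

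Macrophage and monocyte genes rose in 15 of 16 (15 adjusted over the list alone), with the Fc receptor FCGR3A at 4.28 ± 0.56 and complement C1QB at 3.42 ± 0.47 (adjusted p = 0.052 with an estimated correlation). All 3 tested genes of the neutrophil list rose (3 adjusted over the list alone), CSF3R by 3.79 ± 0.46, MNDA by 1.98 ± 0.35 and FCGR3B by 2.33 ± 0.48, with the same adjusted p = 0.052 with an estimated correlation. The other genes of the neutrophil list were not tested, so its result rests on these 3. Of 8 acute inflammatory cytokine genes 8 rose (8 adjusted over the list alone), with the neutrophil chemokine CXCL3 at 4.24 ± 0.41 and CCL4 at 3.29 ± 0.71 (adjusted p = 0.052 with an estimated correlation). Plasma cell genes rose in 10 of 12 (11 adjusted over the list alone), MZB1 by 2.50 ± 0.42 (adjusted p = 0.052 with an estimated correlation). Of 8 B cell genes 0 passed in edgeR, also adjusted over the list alone or at an unadjusted p under 0.05, and 0 in DESeq2 and limma-voom, with CD79A at 0.30 ± 0.48. Dendritic cell genes rose in 1 of 7 (CLEC10A, 1.58 ± 0.30; 1 adjusted over the list alone) and mast cell genes in 2 of 6 (CPA3, 1.66 ± 0.44, and GATA2, 1.60 ± 0.51; 2 adjusted over the list alone), and neither list passed. GATA2 did not pass without colon irAE replicate 10 or healthy colon replicate 1, 2, 3 or 14, at 1.32 to 1.54.

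**Figure D2:**
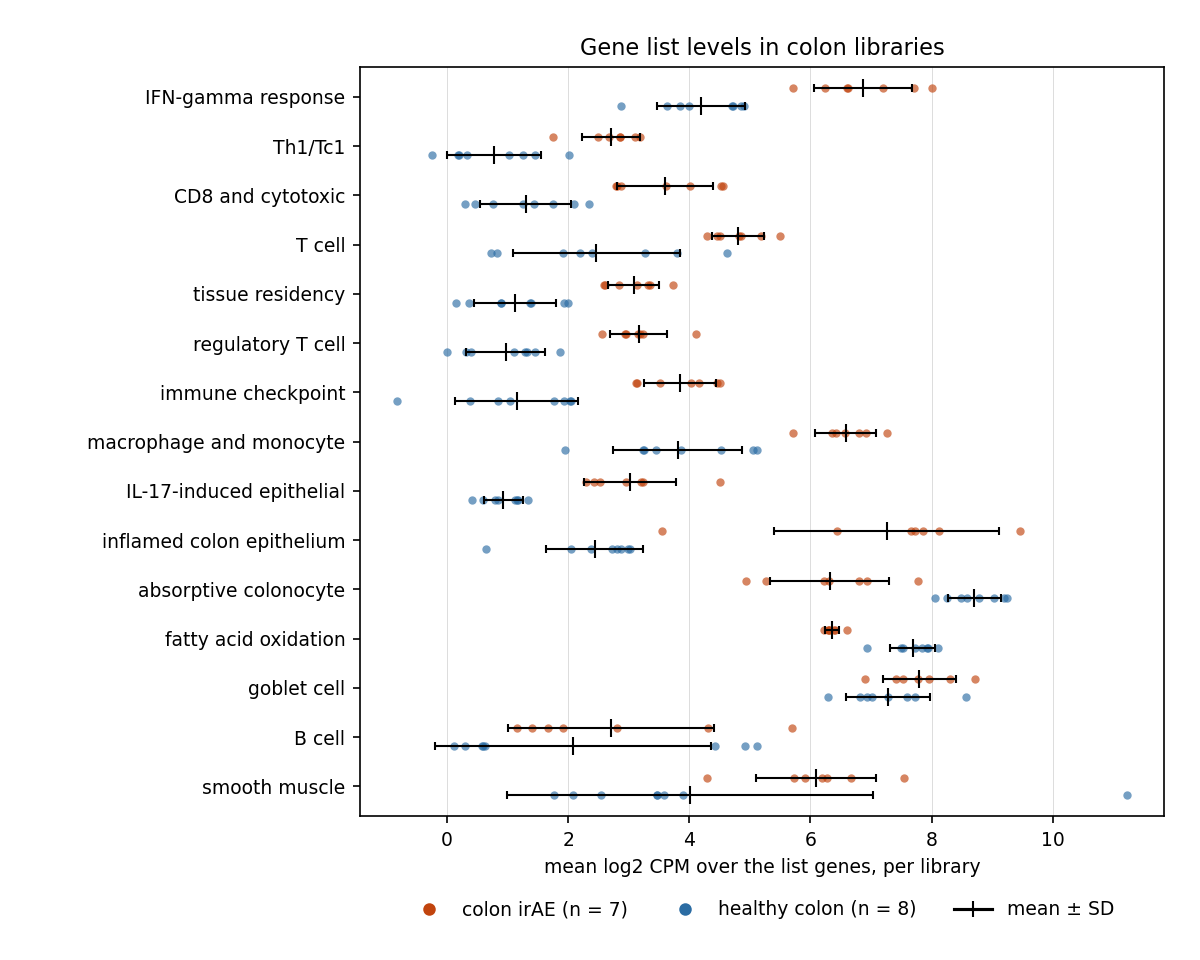
Scores of 15 gene lists in colon, as the mean log2 CPM of the list's genes per library. Each dot is a library, with the mean and SD of 7 colon irAE and 8 healthy colon libraries. The IFN-gamma response score is 6.88 ± 0.81 in irAE and 4.19 ± 0.73 in healthy colon, and the absorptive colonocyte score 6.32 ± 0.98 and 8.71 ± 0.44.

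Antigen presentation genes rose in 6 of 11 for class I (6 adjusted over the list alone), with PSMB9 at 2.07 ± 0.40 and TAP1 at 1.51 ± 0.30 (adjusted p = 0.123 with an estimated correlation). They rose in 6 of 10 for class II (6 adjusted over the list alone), with the invariant chain CD74 at 2.84 ± 0.47 (adjusted p = 0.156 with an estimated correlation). Of 13 inflamed colon epithelium genes 13 rose (13 adjusted over the list alone), including OLFM4 (3.77 ± 0.53) beside DUOX2, DUOXA2 and SAA2, and of 9 IL-17-induced epithelial genes 8 rose (8 adjusted over the list alone), including the siderophore-binding LCN2 (4.11 ± 0.61) and S100A8 (4.95 ± 0.91). Both lists had an adjusted p = 0.052 with an estimated correlation. Absorptive colonocyte genes fell in 9 of 15 (10 adjusted over the list alone), with the chloride exchanger SLC26A3 at -2.58 ± 0.33 and the guanylin gene GUCA2A at -2.87 ± 0.45. Fatty acid oxidation genes fell in 10 of 11 (10 adjusted over the list alone), with ACADM at -1.17 ± 0.23, and both of these lists had an adjusted p = 0.052 with an estimated correlation. Epithelial markers took 2.09% to 3.25% of UMIs in colon irAE and 2.14% to 6.13% in healthy colon.

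After thinning to equal depth, CXCL9 was seen in 20.4% ± 13.5 of spots in colon irAE (SD, n = 7) and in 0.390% ± 0.408 in healthy colon (n = 8; exact permutation p = 0.00016, adjusted p = 0.00062 over 12 genes). GZMB was seen in 12.8% ± 14.2 against 0.925% ± 0.999 (exact permutation, adjusted p = 0.00112) and CD3E in 8.89% ± 3.96 against 2.63% ± 2.64 (adjusted p = 0.0032). CXCL10, CXCL11, TNF, FOXP3, ITGAE and CD69 were also seen in more irAE spots, CD69 in 2.28% against 0.605% (exact permutation, adjusted p = 0.00676). IFNG was seen in 1.04% ± 1.04 against 0.261% ± 0.383 (exact permutation, adjusted p = 0.069), CD8A in 4.63% against 1.66% (adjusted p = 0.0729) and IL17A in 0.261% against 0.217% (adjusted p = 0.798), and these 3 did not pass. Thinning left out 1907 of 4320 healthy spots and 604 of 4370 irAE spots as too shallow. In healthy colon the epithelium-poor spots had the lower median UMIs in each replicate but 13. The spots kept may therefore differ between the groups in tissue make-up, which was not tested. Unthinned, the shares were 44.3% against 1.03% for CXCL9, 6.73% against 0.220% for IFNG, 19.8% against 3.45% for CD8A and 2.0% against 0.354% for IL17A. Olfactory receptor genes, which colon should lack, were seen per gene in 0.083% of thinned irAE spots and 0.100% of healthy ones. At a depth of 3600 UMIs the differences of IFNG and CD8A, 1.94 and 6.98 points, passed (exact permutation, adjusted p = 0.00606 and 0.0137), while that of IL17A, 0.496 points, did not (adjusted p = 0.120). Without colon irAE replicate 9 the GZMB share in irAE was 7.88% and its difference 6.96 points, against 11.9 with it, and passed (exact permutation, adjusted p = 0.002). The IL17A difference of 0.0442 points turned to -0.0318 without irAE replicate 1 and -0.0106 without irAE replicate 6. The IFNG difference of 0.783 points also passed without colon irAE replicate 1 (0.909), 8 (0.956) or 10 (0.886) or healthy colon replicate 14 (0.881), and was 0.471 without irAE replicate 2. The CD8A difference of 2.97 points passed without irAE replicate 1 (3.50) or 9 (3.42) or healthy colon replicate 1 (3.46), and was 1.43 without irAE replicate 6.

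**Figure D3:**
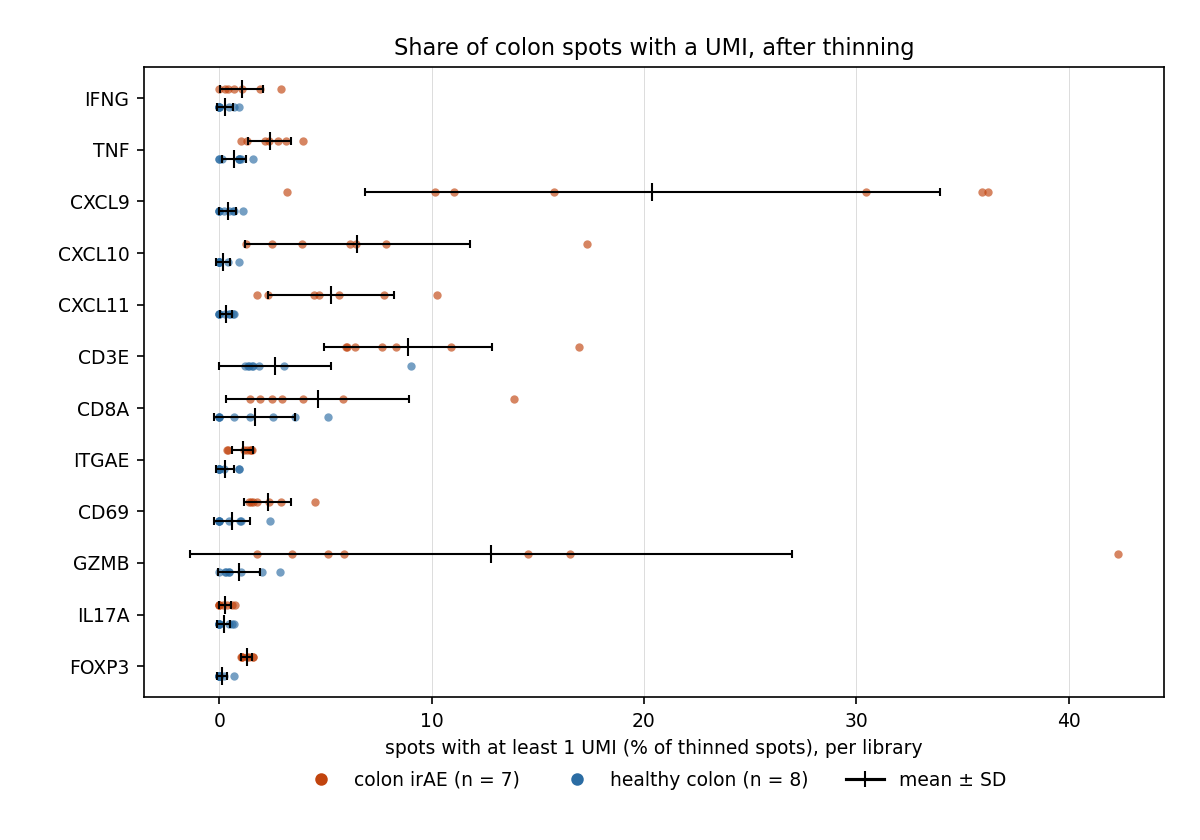
Share of colon spots, thinned to 1800 UMIs, with at least 1 UMI of each of 12 genes, in percent. Each dot is a library, with the mean and SD of 7 colon irAE and 8 healthy colon libraries. CXCL9 reaches 3.18% to 36.2% of irAE spots and at most 1.12% of healthy ones.

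In colon irAE, CXCL9, CXCL10 and CXCL11 were more abundant in spots with a T cell transcript than in the other spots, by a mean log2 ratio of 0.79 ± 0.63 (SD, n = 7; above 0 in 6 of 7 libraries; exact sign-flip p = 0.031). Without any 1 library but replicate 10 the exact p was 0.0625, and the smallest possible with 6 libraries is 0.031. Beside CD8A alone the ratio was 0.43 (exact sign-flip p = 0.281), and over the whole IFN-gamma response list 0.30 (p = 0.0156). In healthy colon the ratio was 2.76 ± 1.27 (n = 8; exact sign-flip p = 0.00781), on 28 chemokine UMIs against 1670 in irAE, and it was 1.04 (exact p = 0.156) with a pseudocount in proportion to the UMIs of both sums, a setting chosen after seeing the data. In skin, where no test was made, the ratios were 1.15 and 0.90 in irAE replicates 8 and 20 and 0.63 and 1.19 in psoriasis replicates 1 and 2, the latter on 8 and 3 chemokine UMIs.

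Across the 7 colon irAE libraries, the tissue residency score rose with the IFN-gamma response score (Pearson r = 0.793, exact permutation p = 0.0369; Spearman rho = 0.893, exact p = 0.0123; adjusted p = 0.0369 over 2 relations). Without the 2 libraries farthest from the median residency score, r was 0.893 (exact permutation p = 0.0583) and rho 1.0 (exact p = 0.0167). With the T cell score subtracted r was 0.66 (exact permutation p = 0.102) and rho 0.607 (exact p = 0.167), and with summed CPM r was 0.779 (exact p = 0.0466) and rho 0.607 (exact p = 0.167). In the 8 healthy libraries r was 0.754 (exact permutation p = 0.0313, adjusted p = 0.0369) and rho 0.691 (exact p = 0.0694). There, r was 0.740 (exact permutation p = 0.0722) and rho 0.771 (exact p = 0.103) without the 2 farthest libraries. With the T cell score subtracted both turned negative, r to -0.592 (exact permutation p = 0.112) and rho to -0.762 (exact p = 0.0368), and with summed CPM r was 0.183 (exact p = 0.670) and rho 0.286 (exact p = 0.501).

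Within colon irAE, epithelium-poor spots were set against epithelium-rich spots of the same libraries to ask where the measured changes lay. MS4A1, the gene of CD20, was higher by 2.05 ± 0.34 and the collagen gene COL1A2 by 0.71 ± 0.15, while AQP8 was lower (-2.52 ± 0.53), as were DUOX2 (-1.65 ± 0.28) and ISG15 (-0.76 ± 0.16). CXCL9, at 0.11 ± 0.27, CXCL10, at 0.05 ± 0.27, and GZMB, at -0.25 ± 0.27, did not pass. In edgeR with the library as a block, 931 genes were higher and 1467 lower in the epithelium-poor spots of irAE among 12009, and 2445 and 2489 in healthy colon. Leaving out colon irAE replicate 1, 2, 5, 8 or 10 gave 492 and 1070, 588 and 1194, 482 and 875, 442 and 968, and 589 and 1224 genes in irAE, and leaving out healthy colon replicate 13, which shares the fit, 1908 and 2322.

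By list, 9 of 10 B cell genes, 10 of 13 fibroblast genes and 7 of 8 smooth muscle genes were higher in the epithelium-poor spots of colon irAE, and 14 of 14 absorptive colonocyte genes lower (median -2.13). Of 19 type I interferon genes 8 were lower and 1 higher, and of 23 IFN-gamma response genes 1 was lower and 0 higher. With an estimated correlation the adjusted p was 0.376 for the B cell, 0.292 for the fibroblast, smooth muscle and absorptive colonocyte and 0.376 for the type I interferon lists. In colon and skin alike, dividing spots on epithelial markers by itself favours lower levels of genes that go with these markers in the epithelium-poor spots. It favours higher levels of other genes there. In healthy colon 14 of 14 absorptive colonocyte genes were lower there too (median -3.09). So were 10 of 19 type I interferon genes, with 1 higher, and 6 of 23 IFN-gamma response genes, with 0 higher. Lower interferon genes in epithelium-poor spots were therefore not particular to irAE. The log2 ratio of epithelium-poor to epithelium-rich spots was higher in irAE than in healthy colon for 148 genes and lower for 50. Among the 148 were HMOX1, a haem-degrading enzyme (-0.14 ± 0.15 in irAE and -2.35 ± 0.19 in healthy colon; edgeR adjusted p of the difference = 0.000223), and CD14, a monocyte receptor (0.37 and -1.15; adjusted p of the difference = 0.0092). HMOX1 and CD14 were chosen after their values were seen. Leaving out colon irAE replicate 1, 2, 6, 8 or 10 gave 41 and 12, 30 and 11, 50 and 11, 92 and 29, and 37 and 13 such genes, and leaving out healthy colon replicate 2, 6 or 13 gave 67 and 22, 95 and 40, and 426 and 394.

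The second comparison set skin irAE against psoriasis, with 2 libraries each. No normal skin was among the libraries. A fall in irAE therefore cannot be told apart from a rise in psoriasis, nor a rise in irAE from a fall in psoriasis. The same chemokines were higher in skin irAE: CXCL9 stood at 1192 CPM against 6.27 (log2 fold change 7.58 ± 0.72, SE), CXCL10 at 446 against 2.82 (7.29 ± 0.52) and CXCL11 at 53.0 against 1.21 (5.44 ± 0.50). The granzymes GZMA (chromosome 5, 55102648 to 55110252) and GZMB rose by 4.95 ± 0.49 and 4.0 ± 0.70, and CCL5 (chromosome 17, 35871491 to 35880793) by 4.57 ± 0.94. Among the largest falls in skin irAE, SERPINB3, a protease inhibitor gene (chromosome 18, 63655197 to 63661963), fell by 8.26 on the log2 scale (SE 1.19) and LCE3D, a late cornified envelope gene (chromosome 1, 152579381 to 152580504), by 6.18 (SE 0.86). IL17A (chromosome 6, 52186375 to 52190638) had 0 counts in skin irAE and 51 in psoriasis, at least 6.80-fold lower against a floor of 3 counts over the group.

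By edgeR's quasi-likelihood test 362 genes were higher and 1245 lower in skin irAE among 12932. Scaled by library size alone, which moved the median log2 fold change of all genes to 0.23, the split was 470 and 791. Without skin irAE replicate 8, edgeR called 1 gene higher, CXCL10, and 0 lower (3173 at an unadjusted p under 0.05), so that each other gene call in skin ended; without replicate 20 it called 1093 and 2386, and without psoriasis replicate 1 130 and 534. DESeq2 called 700 and 1747 and limma-voom 434 and 1162 on all 4 libraries.

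Other large rises in skin irAE were those of GBP5 (4.79 ± 0.90) and the chemokine receptor CXCR3 (4.28 ± 0.85). Several of the largest falls left few counts in irAE. SPRR2F, a small proline-rich protein of the cornified envelope (chromosome 1, 153112114 to 153113515), had 2 counts against 14902 (ratio of psoriasis over irAE 2982, counting interval 825 to 24620), and CHAC1 had 1 against 635 (ratio 254, 45.5 to 10050). IL36A, an epidermal cytokine (chromosome 2, 113005461 to 113008044), had 2 against 893 (ratio 179, 49.3 to 1478) and SRCIN1 3 against 779 (ratio 104, 35.4 to 505). SPRR2B and the proton pump ATP12A fell by 6.83 (SE 0.83) and 6.64 (SE 0.77). Small proline-rich and late cornified envelope genes belong to families of close paralogs, so how their counts divide among members is uncertain. Of the panel, IFNG rose by 2.79 ± 0.71 (edgeR adjusted p = 0.040) and CD69 by 2.57 ± 0.63 (adjusted p = 0.035). The call of IFNG ended without skin irAE replicate 8 (2.10) or psoriasis replicate 1 (2.50) or 2 (3.27), and that of CD69 without irAE replicate 8 (2.32) or psoriasis replicate 1 (2.14). Without irAE replicate 20, CHAC1 and IL36A did not pass, while TNF passed, at 2.55, as it did without psoriasis replicate 2, at 2.38. TNF, at 1.97 ± 0.58 (edgeR adjusted p = 0.062), CD8A, at 0.74 ± 0.78, ITGAE, at -0.78 ± 1.31, CXCR6, at 0.82 ± 0.73, and FOXP3, at 0.55 ± 0.56, did not pass. As psoriasis over irAE per UMI, IL23A, with 12 counts in irAE and 65 in psoriasis, had a ratio of 2.17 (1.16 to 4.41), and IL13, with 2 and 4, had 0.800 (0.115 to 8.85). For IL23A the psoriasis libraries, at 0.617 and 4.60 CPM, lay on both sides of the irAE libraries, at 1.32 and 1.63. The direction of that ratio therefore rests on 1 psoriasis library.

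Camera with the preset correlation called 14 of 35 skin lists higher and 2 lower. With an estimated correlation 0 passed, the smallest adjusted p being 0.676, and fry called 0, so each list call in skin rests on the preset correlation. IFN-gamma response genes rose in 11 of 23 (19 adjusted over the list alone), with GBP1 at 2.81 ± 0.51 (adjusted p = 0.676 with an estimated correlation). T cell genes rose in 8 of 13 (10 adjusted over the list alone), with CD2 at 3.78 ± 0.67 and CD3E at 2.86 ± 0.51. Cytotoxic genes rose in 5 of 14 (9 adjusted over the list alone), with FASLG at 3.12 ± 0.76, and Th1/Tc1 genes in 7 of 13 (11 adjusted over the list alone), with EOMES at 3.75 ± 0.77 and TBX21 at 3.48 ± 0.81. Each of these 3 lists had an adjusted p = 0.676 with an estimated correlation. Immune checkpoint genes rose in 4 of 11 (10 adjusted over the list alone), with CTLA4 at 3.33 ± 0.69. Recirculating lymphocyte genes rose in 2 of 6 (3 adjusted over the list alone), and macrophage and monocyte genes in 5 of 17 (6 adjusted over the list alone), with MRC1 at 3.18 ± 0.52. These 3 had the same adjusted p = 0.676 with an estimated correlation. Without psoriasis replicate 1, GBP1 (2.55), FASLG (2.63), EOMES (3.38) and TBX21 (3.56) did not pass, nor did TBX21 without psoriasis replicate 2 (3.38). In the tissue residency list only CD69 rose, 1 of 8 (2 adjusted over the list alone), and camera did not call it.

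**Figure D4:**
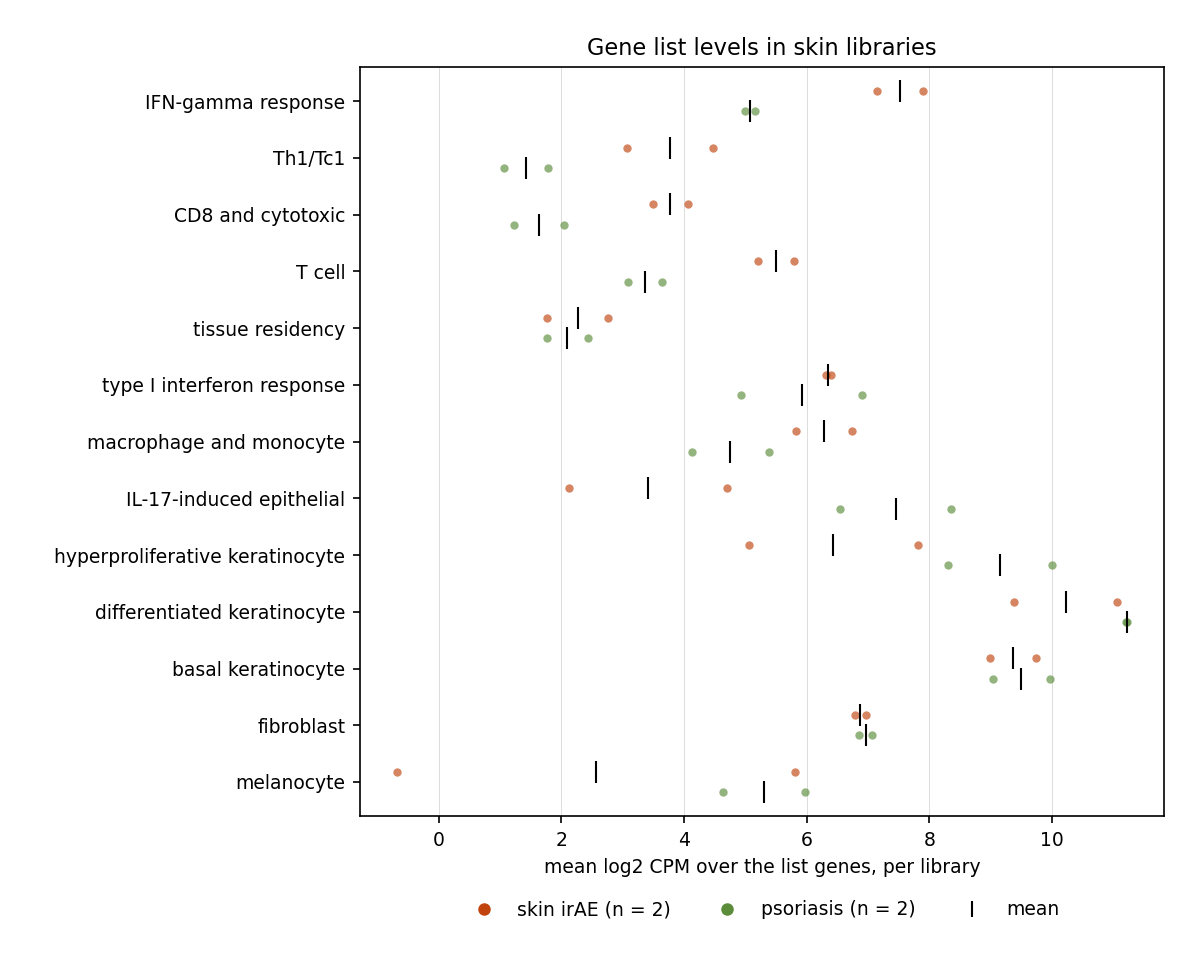
Scores of 13 gene lists in skin, as the mean log2 CPM of the list's genes per library. Each dot is 1 of 2 skin irAE or 2 psoriasis libraries and the bar is their mean, without an error. The IL-17-induced epithelial score is 2.12 and 4.69 in irAE and 6.55 and 8.35 in psoriasis.

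The lists called lower in skin irAE were epidermal. In the IL-17-induced epithelial list 5 of 15 genes fell (6 adjusted over the list alone), among them NFKBIZ (-2.94 ± 0.53) and ZC3H12A (-2.81 ± 0.54), with an adjusted p = 0.717 with an estimated correlation. Its median log2 fold change was -3.06, and -2.94 with IL19, which had 0 counts in irAE, at its bound. In the hyperproliferative keratinocyte list SPRR2B fell, 1 of 8 (1 higher and 3 lower adjusted over the list alone), while KRT6B, at 3.36 ± 1.03, did not pass except without skin irAE replicate 20, at 4.22 (adjusted p = 0.775 with an estimated correlation). Without skin irAE replicate 20 the hyperproliferative list was not called (camera adjusted p = 0.426). Differentiated keratinocyte genes passed in 0 of 11 in edgeR, also adjusted over the list alone, with KRT1 at -2.84 ± 0.80 (1 lower at an unadjusted p under 0.05, 2 lower in DESeq2, 1 in limma-voom). Basal keratinocyte genes passed in 0 of 8 in edgeR (1 higher and 1 lower adjusted over the list alone, at an unadjusted p under 0.05 and in DESeq2, 1 lower in limma-voom), with KRT14 at -2.41 ± 0.70. The basal list had a median of 0.26, a mean of -0.15 and a camera direction of up, and neither keratinocyte list passed. Epithelial markers took 3.85% and 4.43% of UMIs in skin irAE and 6.74% and 7.12% in psoriasis.

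Regulatory T cell genes rose in 4 of 9 and fell in 1 (5 and 1 adjusted over the list alone), with IL2RA at 3.33 ± 0.73 and IKZF2 at -2.45 ± 0.49 (adjusted p = 0.718 with an estimated correlation). Class I presentation genes rose in 1 of 11 (TAP2, 1.87 ± 0.51; 2 adjusted over the list alone; adjusted p = 0.676 with an estimated correlation) and class II genes in 2 of 11 with 1 lower (8 and 1 adjusted over the list alone), with HLA-DMB at 2.24 ± 0.42 (adjusted p = 0.676 with an estimated correlation). Acute inflammatory cytokines rose in 1 of 8 (OSM, 4.14 ± 0.85; 3 adjusted over the list alone) and neutrophil genes in 1 of 9 (MNDA, 2.49 ± 0.49; 3 adjusted over the list alone). Dendritic cell genes rose in 1 of 13 (IL3RA, 1.81 ± 0.49; 2 adjusted over the list alone). These 3 lists had adjusted p = 0.718, 0.676 and 0.718 with an estimated correlation. The call of IL3RA ended without any 1 of the 4 libraries (1.56 to 2.09). Without psoriasis replicate 1, IL2RA (3.11), TAP2 (1.44), HLA-DMB (2.0), OSM (3.77) and MNDA (2.12) did not pass, nor did TAP2 without psoriasis replicate 2 (2.54). In the Th17 list only IL17A passed (1 of 4, as adjusted over the list alone; median -0.29, also with IL17A at its bound), and it did not pass without skin irAE replicate 8 or 20 or psoriasis replicate 1. The Th2 list, 0 of 8 in edgeR and adjusted over the list alone (1 higher at an unadjusted p under 0.05, 0 in DESeq2 and limma-voom), had a median of -0.34, a mean of 0.30, an upward camera and a downward fry direction. The type I interferon list had 0 of 20 passing in edgeR by either count (3 higher and 4 lower at an unadjusted p under 0.05, 3 and 1 in DESeq2, 0 in limma-voom), with MX2 at 2.28 ± 0.65 (3.38, passing, without psoriasis replicate 2), and camera called none of these 3 lists.

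Within skin irAE, 861 genes were higher and 768 lower in the epithelium-poor spots among 12737, and 614 and 146 in psoriasis. T cell genes were higher there in 11 of 13 and macrophage genes in 15 of 17, with CD3E at 1.71 ± 0.33 and CD163 at 1.67 ± 0.19 (adjusted p = 0.431 and 0.308 with an estimated correlation). CXCL9, at 0.79 ± 0.66, did not pass. The log2 ratio of epithelium-poor to epithelium-rich spots was higher in skin irAE than in psoriasis for 1 gene, KYNU (1.97 ± 0.28 and -0.65 ± 0.18), and lower for 16. Among the 16 were TGM3, a transglutaminase of the cornifying epidermis (-2.91 ± 0.33 in irAE and 1.11 ± 0.25 in psoriasis; edgeR adjusted p of the difference = 0.0207), and POSTN, a matrix protein (-1.69 and 1.38; adjusted p of the difference = 0.0171). KYNU, TGM3 and POSTN were chosen after their values were seen. Over spots with at least 500 UMIs, edgeR called this difference for 0 genes higher and 5 lower (948 at an unadjusted p under 0.05; other tools were not run), and between the outer parts of a 3-part division for 1 and 50. Epithelial markers took 1.17% and 1.84% of UMIs in the epithelium-poor spots of skin irAE replicates 8 and 20. In those of psoriasis replicates 1 and 2 they took 3.78% and 3.52%. There, 3 of 15 IL-17-induced epithelial and 1 of 9 hyperproliferative keratinocyte genes were higher and 0 lower. Of 7 differentiated keratinocyte genes 1 was lower. The parts thus differed between groups in their share of these markers, and how far this sets the differences was not tested. Thinning skin spots to 900 UMIs left out 513 of 1155 in irAE and 104 of 951 in psoriasis, and kept 204 of 695 in irAE replicate 8. In the thinned spots of skin irAE replicates 8 and 20, CXCL9 was seen in 61.3% (exact binomial 95% interval 54.2% to 68.0%) and 38.8% (34.2% to 43.6%), and in psoriasis replicates 1 and 2 in 1.06% (0.344% to 2.45%) and 0.267% (0.0068% to 1.48%). Unthinned, the shares were 59.0% and 78.9% in irAE and 5.20% and 10.4% in psoriasis.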

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

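The tests of chance, of depth and of the pseudocount given here, with their bounds, were chosen after the results were seen. Of 170 sets of values tested for a library far from the others of its group, 16 had one, and chance gives about 1 in 20 sets, or 5%.

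In colon irAE, replicate 9 had 57.7% of its spots under 500 UMIs, the others 0% to 4.22%. It also had the largest shares of thinned spots with CXCL10 (17.3%, the others 1.27% to 7.87%) and GZMB (42.3%, the others 1.78% to 16.5%). Colon irAE replicate 6 had the highest IL-17-induced epithelial score (4.50, the others 2.29 to 3.24) and the largest share of thinned spots with CD8A (13.9%, the others 1.43% to 5.82%).

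In healthy colon, replicate 13 stood highest in the smooth muscle score (11.2, the others 1.77 to 3.90), the fibroblast score (7.95, the others 3.64 to 5.34) and the enteric glia and nerve score (4.72, the others -0.31 to 1.17). Replicate 10 stood lowest in the class I presentation score (5.78, the others 7.17 to 8.08), in the inflamed colon epithelium score (0.637, the others 2.06 to 3.03) and in DUOX2 (-2.10 log2 CPM, the others 2.45 to 4.38). Replicate 6 stood lowest in CD8A (-2.10 log2 CPM, the others 1.67 to 4.29). These values of DUOX2 and CD8A are the floor set by the prior count, so their distance from the others depends on it. Replicate 14 had the largest shares of thinned spots with CXCL10 (0.948%, the others 0% to 0.421%), CD3E (9.0%, the others 1.19% to 3.06%) and CD69 (2.37%, the others 0% to 1.02%), and replicate 15 the largest with FOXP3 (0.676%, the others 0% to 0.225%).

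The effect of epithelium-poor against epithelium-rich spots differed between colon irAE and healthy colon for 198 genes and, with the preset correlation, for 9 lists, and between skin irAE and psoriasis for 17 genes and 11 lists. With an estimated correlation 0 of these lists passed in camera, the smallest adjusted p being 0.837 in colon and 0.711 in skin. A chance division of the libraries was argued against for the 198 genes. Of 40 regroupings of the colon libraries 1, the real one, reached that number, the smallest share that 40 allow, and 0 genes were called in any other. The regroupings do not bear on what differs between the groups, such as how sharply the spots divided. Within colon irAE the real division called 2398 genes, and the highest of the other 39 random exchanges of the parts within libraries 427, so that 1 of 40 reached the real number. Within healthy colon the values were 4934, 3474 and 1 of 40. The parts were divided on epithelial expression, which sets the outcome of such exchanges, and these counts do not bear on chance.

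The log2 ratio of CXCL9, CXCL10 and CXCL11 beside T cell transcripts was lower in colon irAE than in healthy colon by a difference of -1.98 (exact permutation p = 0.00435). With a pseudocount in proportion to the UMIs of both sums the difference was -0.254 (exact permutation p = 0.744), which is consistent with the fixed pseudocount as a source of the larger healthy ratio. The pseudocount alone, with 0 chemokine UMIs in both sums, would give 2.94 in healthy colon, against the 2.76 measured. In 6 of 8 healthy libraries at least 1 of the 2 sums was 0. A biological difference between the groups in the same direction stays untested at these counts.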

How the results depend on the processing

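The lists of settings were fixed in advance, except those named here as chosen after seeing the data. Unless a clause says otherwise, the cause of a change was not tested. A term for the slide or capture area was not run, since no slide was named. Depth limits low genes most in healthy colon, where totals ran down to 693082 UMIs, and in skin, where 2 libraries per group left 2 residual degrees of freedom.

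Of 1410 genes higher and 1576 lower in colon irAE, fewer were called with a minimum mean of 20 CPM, which tests fewer genes (937 higher), and with log library size in the fit (22 higher, 33 lower). More were called by limma-voom (2953 and 2604), and mean log-normalised spots moved the split (5547 and 181), with 442 of the 2986 calls changing sign and 53% shared, as did scaling by library size alone (982 lower). Settings chosen after seeing the data gave 625 and 540 without the 4 shallowest healthy libraries, 819 lower with the smooth muscle score in the fit, 659 lower with olfactory receptor levels in it, and 483 and 620 in the epithelium-poor spots. DESeq2, its size factors in edgeR, no count filter, spots with at least 500 UMIs, thinned libraries, removal of immunoglobulin genes, 1 fit of all 4 groups and each library left out (1067 to 2079 higher, 1175 to 1986 lower) kept both counts within 1.5 times. Of the 20 colon lists higher and 2 lower, 0 and 0 were called with an estimated correlation, and 13 higher with thinned libraries, which tested fewer genes.

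The replicate number is no evidence of pairing: deviations of libraries with the same number correlated at -0.205, -0.083, -0.519 and -0.183 for numbers 1, 2, 6 and 10, and no library correlated best with its own number. With that number as a block in the 8 libraries that share 4 numbers, edgeR called 0 genes higher and 1 lower (2089 at an unadjusted p under 0.05), and without the block, on the same libraries, 748 and 295. DESeq2 and limma-voom were not run on these 8 libraries. Camera called 25 lists higher and 2 lower in both of these fits.

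Of 362 genes higher and 1245 lower in skin irAE, more were called without a count filter (783 and 2203) and by DESeq2 (700 higher). Fewer were called in 1 fit of all 4 groups (63 and 68), with scaling by library size alone (791 lower) and in the epithelium-rich spots, chosen after seeing the data (188 higher). On mean log-normalised spots limma called 0 and 0 (1234 at an unadjusted p under 0.05). Leaving out 1 library gave 1 to 1093 higher and 0 to 2386 lower, the lowest without skin irAE replicate 8 and the highest without replicate 20. Where 1 library was left in a group, it was assumed to vary like the other group. Of 14 skin lists higher and 2 lower, 0 and 0 were called with an estimated correlation and 0 and 0 by fry, 1 lower in the epithelium-rich spots, and 2 to 4 lower with 1 library left out.

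The difference between colon groups in the share of spots was 6.51 points for IFNG, 16.3 for CD8A and 1.65 for IL17A without thinning, which keeps the difference in depth, and 1.94 for IFNG and 6.98 for CD8A at 3600 UMIs, and all of these passed. With 1 library left out, the IFNG difference ran from 0.471 to 0.956 that of CD8A from 1.43 to 3.50 and that of IL17A, which did not pass, from -0.032 to 0.110. The chemokine ratio beside T cells in colon irAE was 0.432 beside CD8A alone and 0.595 to 0.925 with 1 library left out. In healthy colon it was 0.755 unthinned and 1.04 with the proportional pseudocount, and did not pass in these 2. Beside CD8A alone it was 3.73, where 5 libraries allow no exact p under 0.0625, the value found. The difference between groups was -3.30 beside CD8A alone, with 5 healthy libraries and the fixed pseudocount (exact permutation p = 0.00126). The proportional pseudocount was not run beside CD8A alone, so that p does not separate a group difference from the pseudocount. The difference was 0.318 unthinned, the opposite sign, -0.148 over the IFN-gamma response list and -0.254 with the proportional pseudocount.

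The correlation of the residency and IFN-gamma response scores in colon irAE missed the threshold in Pearson's r without the 2 farthest libraries (0.893, n = 5), where Spearman's rho passed (1.0), and in both with the T cell score subtracted (r 0.66, rho 0.607). With summed CPM r passed (0.779) and rho did not (0.607). In healthy colon it was 0.183 with summed CPM and 0.74 without the 2 farthest libraries, and -0.592, the opposite sign, with the T cell score subtracted, where rho, at -0.762, passed.

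Between epithelium-poor and epithelium-rich spots, genes higher and lower in colon irAE numbered 442 to 1908 and 875 to 2322 with 1 library left out. The difference between colon groups was called for 30 to 426 and 11 to 394 genes with 1 library left out, and for 86 and 25 between the outer parts of a 3-part division. In psoriasis that division gave 1119 and 265, and spots with at least 500 UMIs gave 92 lower. The difference between skin groups was called for 50 lower with the 3-part division. With at least 500 UMIs edgeR called 0 higher and 5 lower (948 at an unadjusted p under 0.05), and other tools were not run on it.

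Among the genes that the naming rule takes, less those not reported here, 53 of 4551 comparisons with a setting changed sign in colon and 38 of 2354 in skin, whether or not the gene passed. In colon 4051 kept sign and side of the threshold, 376 lost the call and 71 gained it, and in skin 1922, 249 and 145. Lost calls were most frequent with log library size (88), the replicate block (98), mean log-normalised spots in skin (60) and without skin irAE replicate 8 (59).

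Smooth muscle and nerve genes of colon changed sign without healthy colon replicate 13. With 1 library left out, ACTG2 ran from -3.07 to 3.98, CNN1 from -3.31 to 4.44, MYLK from -2.87 to 0.51, SYNPO2 from -2.78 to 2.15, CDH19 from -1.02 to 1.81, NCAM1 from -0.40 to 1.55, CD22 from -0.70 to 0.95 and CD79A from -0.009 to 0.57. DESeq2 gave 2.63 for ACTG2, 3.37 for CNN1, 0.48 for MYLK, 1.94 for SYNPO2, 1.51 for CDH19 and 1.32 for NCAM1, and limma-voom 3.88, 4.41, 0.015, 1.49, 1.85 and 1.53. On the 8 libraries with shared numbers the block gave 4.47, 4.60, 0.17, 1.60, 1.65 and 1.54. The fit of these 8 without a block gave 3.72 for ACTG2, 4.23 for CNN1, 1.54 for SYNPO2, 1.57 for CDH19, 1.35 for NCAM1 and 0.11 for HSPA1A. With the smooth muscle score in the fit ACTG2 was at 0.36, CNN1 at 0.595, CDH19 at 0.015, NCAM1 at 0.15 and NEUROD1 at 0.050.

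Log library size in the colon fit turned AGR2 (-0.086), MMP2 (-0.041), ATF3 (-0.11), AXIN2 (0.16), COL1A2 (-0.064), HBA2 (-0.80), HSPA1A (0.058), IL3RA (-0.052), LUM (-0.70) and S100B (-0.96). Mean log-normalised spots of colon turned ACTG2 (0.169), EPHB2 (0.10), HSPA1B (0.090), TPH1 (0.027) and NCAM1 (0.015). In the epithelium-rich spots ASCL2 was at 0.14.

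In skin, with 1 library left out, these genes took both signs: BANK1 (-2.22 to 0.165), CD8A (-0.082 to 1.55), CMA1 (-3.17 to 0.36), COL17A1 (-0.067 to 1.85), FABP4 (-1.90 to 2.49), FOXP3 (-0.14 to 1.04), HBA1 (-13.1 to 2.93), HBA2 (-7.04 to 5.76), HPGDS (-2.02 to 0.29), IGHA1 (-3.11 to 1.70), IL1RL1 (-1.67 to 0.097), ITGAE (-6.97 to 0.39), KRT77 (-2.70 to 2.69), MITF (-0.71 to 1.08), MLANA (-12.1 to 0.45), MS4A1 (-0.58 to 3.58), PLIN4 (-5.24 to 0.82), POU2AF1 (-1.15 to 2.81) and SCGB1D2 (-4.36 to 7.45). Limma-voom turned FABP4 (1.07), HBA2 (0.62), KRT77 (-0.13) and SCGB1D2 (2.59), and mean log-normalised spots CD8A (-0.004), CXCR6 (-0.006), KLRB1 (-0.002), KLRC1 (-0.003), KRT77 (-0.033), MS4A1 (-0.012), NCAM1 (-0.009) and POU2AF1 (-0.001). The epithelium-poor spots turned KRT77 (-1.29), and the epithelium-rich spots CDH19 (0.020), FOXP3 (-0.21) and HPGDS (0.082).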

Other observations

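The tests that weigh explanations here, with their bounds, were chosen after the results were seen, while the gene lists and their tests were fixed in advance. In colon irAE, genes of vessels, of matrix turnover and of dividing cells rose, by the counts that follow. Endothelial genes rose in 7 of 11 (8 adjusted over the list alone), with PLVAP, a diaphragm protein of fenestrated vessels, at 1.97 ± 0.38 and VWF, the von Willebrand factor gene, at 2.46 ± 0.52 (camera adjusted p = 0.118 with an estimated correlation). Matrix remodelling genes rose in 5 of 8 (5 adjusted over the list alone), with the macrophage elastase MMP12 at 4.53 ± 0.99, the plasminogen activator PLAU at 2.72 ± 0.59 and TIMP1 at 2.56 ± 0.57 (adjusted p = 0.123 with an estimated correlation). Fibroblast genes rose in 2 of 13, PDGFRA (1.49 ± 0.47) and MMP2 (1.57 ± 0.55), and in 0 adjusted over the list alone in edgeR (4 at an unadjusted p under 0.05, 3 in DESeq2, 11 in limma-voom). The adjusted p was 0.428 with an estimated correlation. Healthy colon replicate 13 stood apart in the fibroblast score (7.95, the others 3.64 to 5.34), and without it PDGFRA was at 2.11 and MMP2 at 2.43. Without the 4 shallowest healthy libraries they were at 0.84 and 0.82 and did not pass. Proliferation genes rose in 11 of 15 (12 adjusted over the list alone), with RRM2 at 2.06 ± 0.33 and CDK1 at 1.41 ± 0.22 (adjusted p = 0.096 with an estimated correlation). Goblet cell genes went both ways, 3 higher and 1 lower of 14 (3 and 1 adjusted over the list alone): SPINK4 (3.60 ± 0.62), TFF3 (1.33 ± 0.44) and AGR2 (1.86 ± 0.66) rose and ZG16 fell (-1.51 ± 0.49), and the list did not pass. Of these genes, 1 left-out library at a time ended the call of MMP2 for 11 libraries (1.38 to 1.64), AGR2 for 9 (1.44 to 1.88), TFF3 for 9 (1.06 to 1.37), ZG16 for 7 (-1.47 to -1.38) and PDGFRA for 4 (1.3 to 1.41).

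Camera called none of the other colon lists, and in those with 0 genes passing, 0 passed adjusted over the list alone. In the crypt stem cell list 0 of 7 genes passed in edgeR (1 higher and 1 lower at an unadjusted p under 0.05, 1 lower in DESeq2, 1 higher and 2 lower in limma-voom), with AXIN2 at -1.06 ± 0.39 (passing without colon irAE replicate 10, at -1.38, or healthy colon replicate 1, at -1.16, or 13, at -1.23). In the enteroendocrine list 0 of 8 passed in edgeR (0 unadjusted, 0 in DESeq2, 3 lower in limma-voom), with INSL5 at 1.52 ± 1.14 (3.77, passing, without healthy colon replicate 2). Of 8 smooth muscle genes 0 passed in edgeR (1 lower at an unadjusted p under 0.05), while DESeq2 called 7 and limma-voom 6 higher. The median of that list was -2.23 and its mean -1.94, against an upward camera direction and a score difference of 2.08, and healthy colon replicate 13 held the highest smooth muscle score. Of 4 enteric glia and nerve genes 0 passed in edgeR (0 unadjusted, 2 higher in DESeq2, 3 in limma-voom). Of 9 immediate early and heat shock genes JUN fell (-1.09 ± 0.36), 0 adjusted over the list alone in edgeR (2 lower unadjusted, 1 higher and 1 lower in DESeq2, 1 and 2 in limma-voom). The call of JUN ended for 8 libraries left out 1 at a time (-1.09 to -0.88). That list had a median of -0.09, a downward camera direction, an upward fry direction and a score difference of 0.35. The NK cell list had 1 tested gene, NCAM1 (-0.22 ± 0.71; 0 at an unadjusted p under 0.05 in edgeR, 1 higher in DESeq2 and limma-voom, and 1.55 without healthy colon replicate 13), and a score higher by 0.96 over 6 genes (exact permutation, adjusted p = 0.00256). The NK cell score rests mostly on genes under the count filter, so it may differ with library depth, which was not tested. The eosinophil list had 0 tested genes and scores of -0.45 and -1.29 (exact permutation, adjusted p = 0.0571), and the red blood cell list had HBA2 at 1.24 ± 0.74 (2.19, passing, without healthy colon replicate 13; 0 in edgeR unadjusted and in DESeq2, 1 higher in limma-voom).

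In skin irAE, matrix remodelling genes rose in 3 of 10 (4 adjusted over the list alone), with TIMP1 at 2.74 ± 0.41 and the matrix glycoprotein TNC at 1.94 ± 0.38 (adjusted p = 0.676 with an estimated correlation). Endothelial genes went both ways, 2 higher and 1 lower of 12 (2 and 1 adjusted over the list alone): the adhesion receptor SELE (2.50 ± 0.55) and ENG (1.64 ± 0.40) rose and EGFL7 (-2.90 ± 0.66) fell. Of 9 immediate early and heat shock genes HSPA1A (-2.40 ± 0.45) and IER2 (-2.16 ± 0.42) fell (3 adjusted over the list alone). The mast cell tryptase gene TPSB2 fell (-3.35 ± 0.81), 1 of 9 (1 adjusted over the list alone). SDC1, shared by plasma cells and keratinocytes, fell (-2.29 ± 0.45), 1 of 11 plasma cell genes (1 adjusted over the list alone), as did the gland gene MUCL1 (-3.16 ± 0.69), 1 of 4 eccrine genes (2 adjusted over the list alone). Of 13 fibroblast genes THY1 rose (2.12 ± 0.50; 1 adjusted over the list alone), with a median of -0.11, a mean of -0.02 and an upward camera direction. Without psoriasis replicate 1, TNC (2.21), ENG (2.01), EGFL7 (-2.46), HSPA1A (-1.84), IER2 (-1.72), TPSB2 (-3.22) and THY1 (1.94) did not pass, nor did TNC (1.72), ENG (1.34) and SELE (2.10) without psoriasis replicate 2, and none of the genes named here passed without skin irAE replicate 8. Camera called none of these lists but matrix remodelling.

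The other skin lists had 0 genes passing in edgeR, also adjusted over the list alone except where given, and camera called none of them. Of 15 proliferation genes 4 were higher and 1 lower at an unadjusted p under 0.05 (2 higher in DESeq2, 0 in limma-voom), with UBE2C at 1.14 ± 0.36. Of 8 smooth muscle genes 1 was higher by each of the 3 counts, with ACTG2 at 2.63 ± 0.77. Of 6 enteric glia and nerve genes 1 was higher by each of the 3 counts and adjusted over the list alone, with S100B at 1.58 ± 0.45, a median of -0.26, a mean of -0.30 and an upward camera direction. Of 3 B cell genes 1 was higher unadjusted, in DESeq2 and adjusted over the list alone (0 in limma-voom), CD79B at 2.10 ± 0.67. Of 3 NK cell genes 1 was higher unadjusted (0 in DESeq2 and limma-voom), with NCR1 at 2.09 ± 0.84. Adipocyte (5 tested), melanocyte (7), red blood cell (2) and eosinophil (1) genes had 0 by each of these counts in edgeR, DESeq2 and limma-voom, with PLIN1 at -2.22 ± 1.45, PMEL at -2.09 ± 1.10, HBA1 at -5.03 ± 2.83 and PRG2 at -1.27 ± 0.64. The eosinophil score over 5 genes was higher in skin irAE by 0.87. With 1 library left out, UBE2C (1.18), ACTG2 (3.09) and PMEL (-4.90) passed without skin irAE replicate 20, ACTG2 (3.88) without psoriasis replicate 1, and S100B (2.09) and HBA1 (-6.06) without psoriasis replicate 2.

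For the 2986 genes called between colon groups a chance division of the libraries was argued against. Of 100 regroupings 1, the real one, reached that number, and the highest other called 1846 genes. For the 22 lists called with the preset correlation chance was not excluded, with 10 of 100 regroupings reaching that number and 30 lists in the highest other. Fewer counted molecules in the healthy libraries were argued against as the whole cause by thinning to equal totals, after which 80.2% of the called genes still tested (1862 of 2322) kept call and sign. A sample quality that goes with library size cannot be told apart from the group, since the totals of the groups differed. With log library size in the fit the median size of the called genes' log2 fold change went from 1.22 to 0.877 and the median SE from 0.306 to 0.485, both of which end calls, so that 44 calls were shared and 63 signs changed.

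The lower IL-17-induced epithelial list in skin irAE may reflect a difference between dermatitis and psoriasis, as a hypothesis from 2 libraries per group that stays open to differences between donors or sites, which were not tested. A smaller keratinocyte share in irAE sections was argued against as the whole cause, as far as differentiated keratinocyte genes measure that share. In the epithelium-rich spots the IL-17-induced list's median log2 fold change was lower than that of the differentiated list by a difference of -2.75. That fit left out the epithelial markers, KRT1 and KRT10 among them, so the differentiated list was incomplete there. Over whole sections, with all 11 differentiated genes, the medians were -3.06 and -0.72. Whether psoriasis itself changes the differentiated genes was not tested. A single aberrant irAE library was argued against as the whole cause by leaving out each, after which the higher of the medians was -3.14, without replicate 20, and the lower -6.32, without replicate 8. In the latter fit edgeR called 0 genes of the list, as only 1 gene of all tested passed.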
